A study of Mus musculus with 6 samples.

How the data were processed

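The transcriptome of epididymal white adipose tissue was measured by bulk RNA sequencing in male C57BL/6J mice aged 16 weeks. Mice were either fed normally or deprived of food for 24 h, with 3 mice in each group per the series' design text. Libraries were grouped by the treatment label, and replicate numbers are in accession order and pair no fed with any fasted mouse. Per the labels' protocols, RNA was extracted with Trizol from weighed pieces of tissue and libraries were made with standard Illumina methods.

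Per the file headers, the values deposited for each library are FPKM (fragments mapped to a gene, scaled to its transcript length and to the mapped total), given with at most 2 decimals. Per the submitters' processing notes, RSEM and the mouse builds mm10 and GRCm38.p6 were used. The version of RSEM, the aligner and the annotation release are not given in the sources used here. Because of the rounding, the smallest non-zero value in each library was 0.01 or 0.02, and the value of a single read could not be recovered. Depth per library is therefore unknown, and no counting interval is given. FPKM values carry no strand information here, so reads of overlapping genes on opposite strands could not be separated.

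Each file held the same 3162 gene identifiers. Of these, 3158 matched the GRCm38 annotation used here and 4 did not; 3152 were protein-coding, of the 21951 protein-coding genes and 55450 genes of all kinds in that annotation. Symbols and coordinates come from this annotation. In 2953 of the 3162 genes (93.4%) the fed and fasted values did not overlap, where chance gives 10%. Ratios of group means near 1 were almost absent. The genes held are therefore a set chosen for differing between these same 6 libraries, by a rule that is not stated in the sources used here. All other genes were not analysed here, so a gene's absence from the text carries no information about it.

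Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean) on log2(FPKM + 1), for the 2999 genes with a mean of at least 1 FPKM over the 6 libraries. A further 163 genes were below that mean. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 2999 genes, with a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and each is given with its standard error. Because the genes had been chosen on the same libraries, this adjustment does not measure a genome-wide false discovery rate. A stricter adjustment was added after the data were examined. It gave each gene not tested here the largest possible p, over all protein-coding genes or over all annotated genes.

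Gene lists were fixed before the data were examined: 25 of pathways or processes and 14 of cell types. The 26 lists with at least 5 measured members were compared with all other tested genes by camera, from limma, with a preset correlation between genes of 0.01. Camera was repeated with a correlation estimated per list, and fry was run as a test of a different question, whether the genes of a list move one way on balance against no change. Both camera forms compare a list with other chosen genes, not with the whole transcriptome. Enrichment of lists among the chosen genes was not tested because the background of the choice is unknown. Counts of list members are given from the test over all genes and, where it differs, adjusted over the list alone. No list was held in full, so these counts cover only its measured members.

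The genes named in the text were set by a rule fixed before the data were examined. It took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, leaving out predicted genes and genes with no symbol. It added up to 4 members of each list with the smallest p, and Lep, Adipoq, Pdk4, Angptl4, Irs2, Fasn, Scd1, Srebf1, Pck1, Pnpla2, Lipe and Ucp1 whatever their result. Adipoq, Scd1, Pck1, Pnpla2, Lipe and Ucp1 were not analysed here. Other genes named were chosen after their values were seen, and this is stated with them. Values of some genes that the rule takes are not reported here.

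The test was tried on simulated data of 2999 genes with 200 changed. It recovered 22.5% of genes changed by 0.5 on the log2 scale, 72.5% of those changed by 1 and 100% of those changed by 2. The 128 calls included 12 unchanged genes, a larger share than the adjusted p threshold. In the data 2714 of the 2999 genes passed, so the adjustment was looser there than with 200 changed genes. The shares recovered in the simulation therefore do not measure the power of the test in these data. A second simulation drew 20000 unchanged genes and kept the 1059 with an unadjusted p under the threshold. Adjusted over the kept genes alone, 979 of them (92.4%) passed. By limma none passed (0) when the remaining genes were given the largest possible p.

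Alternatives fixed in advance were limma without the trend or with robust variances, median-ratio and quantile scaling, no filter, a minimum mean of 5 FPKM, a pseudocount of 0.1, a minimum log2 fold change of 1 in size, and leaving out each library in turn. Added later were the stricter adjustments and a shift of the fasted libraries by 0.118 on the log2 scale, the midpoint of the nearly empty interval of ratios. Median-ratio and quantile scaling assume that rises and falls balance, which is not known for a chosen set of genes.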

Results

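Epididymal white adipose tissue, the visceral fat depot around the epididymis of male mice, was sequenced from 3 fed mice and 3 mice fasted for 24 h. The comparison addressed how short food deprivation alters transcription and lipid metabolism in this depot. Summed FPKM over the 3162 genes held was 190380, 209200 and 197540 in the fed libraries and 188060, 184550 and 180060 in the fasted libraries. These sums cover chosen genes and are not sequencing depths, which are unknown. Spearman correlations between libraries were 0.9735 to 0.9855 within a group and 0.8324 to 0.9261 between groups. The separation of groups is partly built in, because the genes had been chosen for differing between these libraries.

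Of 2999 genes tested, 1232 were higher and 1482 lower in fasted than in fed tissue (limma, Benjamini-Hochberg). Higher genes made up 45.4% of calls. With median-ratio scaling the counts were 1237 and 787, and higher genes made up 61.1% of calls. At least a doubling or halving of FPKM + 1 was reached by 340 of the higher and 348 of the lower genes, against 564 and 236 with median-ratio scaling, 254 and 431 with the fasted libraries shifted, and 493 and 439 with a pseudocount of 0.1. Under the stricter adjustment over all annotated genes, 172 were higher and 192 lower. The median log2 fold change over the tested genes was -0.34, and it moved to -0.15 with median-ratio scaling, -0.21 with quantile scaling and -0.45 with the fasted libraries shifted. Across these scalings 1207 to 1237 genes were higher and 787 to 1733 lower. The wider range for falls is partly built in by the choice of genes. Positive ratios of group means held began near 0.45 on the log2 scale, and negative ones near -0.21. In the main fit 8 positive and 277 negative changes were not called, so few rises were left to gain.

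**Figure D1:**
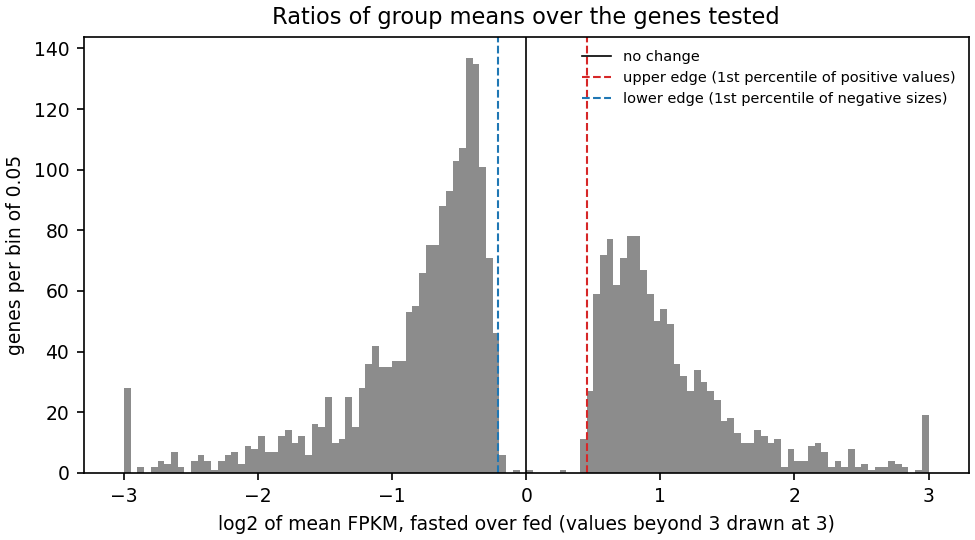
Histogram of the log2 ratio of mean FPKM, fasted over fed, for the 2999 genes tested, in genes per bin of 0.05; dashed lines mark edges at -0.21 and 0.45, which 1% of the negative and 1% of the positive ratios lie inside. Only 8 genes had a log2 ratio within 0.2 of 0, and the midpoint of the edges was 0.118 rather than 0.

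On the log2(FPKM + 1) scale, the deepest fall was that of Lep, which encodes the satiety hormone leptin. It went from 430 ± 229 to 12.8 ± 7.46 FPKM (mean ± SD, n = 3 per group), a log2 fold change of -5.01 ± 0.49 (SE; limma adjusted p = 0.000565). Lep (ENSMUSG00000059201) lies on the plus strand of chromosome 6 at 29060220 to 29073877 (GRCm38). Pnpla3, a lipid droplet acyltransferase and hydrolase gene on chromosome 15 (84167837 to 84187236), went from 362 ± 95.4 to 10.9 ± 3.94 FPKM (log2 fold change -4.95 ± 0.26). Dgat2, the diacylglycerol acyltransferase of triglyceride synthesis, went from 1151 ± 555 to 78.4 ± 36.3 FPKM (-3.85 ± 0.39). Fasn, fatty acid synthase, went from 437 ± 337 to 36.6 ± 7.33 FPKM (-3.25 ± 0.52). The other genes among the 10 deepest falls were Cdsn (-4.04 ± 0.51), the collagen gene Col15a1 (-3.56 ± 0.32), the oxytocin receptor gene Oxtr (-3.28 ± 0.25), the creatine synthesis gene Gamt (-3.27 ± 0.20), Trabd2b (-3.19 ± 0.18) and the desaturase gene Scd2 (-3.08 ± 0.59). Without fed replicate 2, the change was -2.65 for Fasn and -2.39 for Scd2. Scd2 alone among these 10 missed the adjustment over all annotated genes (adjusted p = 0.0778).

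The largest rise on the same scale was that of Apoc3, an apolipoprotein gene on the minus strand of chromosome 9 at 46232933 to 46235636 (GRCm38). It went from 4.07 ± 2.22 to 92.1 ± 46.1 FPKM, a log2 fold change of 4.17 ± 0.49 (limma adjusted p = 0.000973). The imprinted gene Peg3 went from 13.5 ± 6.47 to 132 ± 58.1 FPKM (3.23 ± 0.43). Cytl1 (3.27 ± 0.42), the F-box gene Fbxo31 (2.71 ± 0.34), the mitochondrial carrier gene Slc25a34 (2.90 ± 0.50) and the chemokine gene Ccl21a (2.84 ± 0.63) also rose, as did the cytochrome P450 gene Cyp2b10 (3.07 ± 0.84). The rise of Cyp2b10 was 2.02 without fasted replicate 2, which alone had 88.0 FPKM, and 3.74 without fasted replicate 3. That of Slc25a34 was 2.27 without fasted replicate 2, and that of Ccl21a was 3.53 without fed replicate 1 and 2.16 without fed replicate 2. Chchd10 (2.99 ± 0.31), a mitochondrial protein gene, and the metalloproteinase gene Mmp11 (2.90 ± 0.21) rose as well. They lie on opposite strands of chromosome 10 with overlapping exons, so their values may share reads. Cyp2b10 and Ccl21a have near-identical relatives and are uncertain for that reason. Over all annotated genes, Cyp2b10 (adjusted p = 0.22), Ccl21a (0.119) and Slc25a34 (0.0574) missed the threshold.

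**Figure D2:**
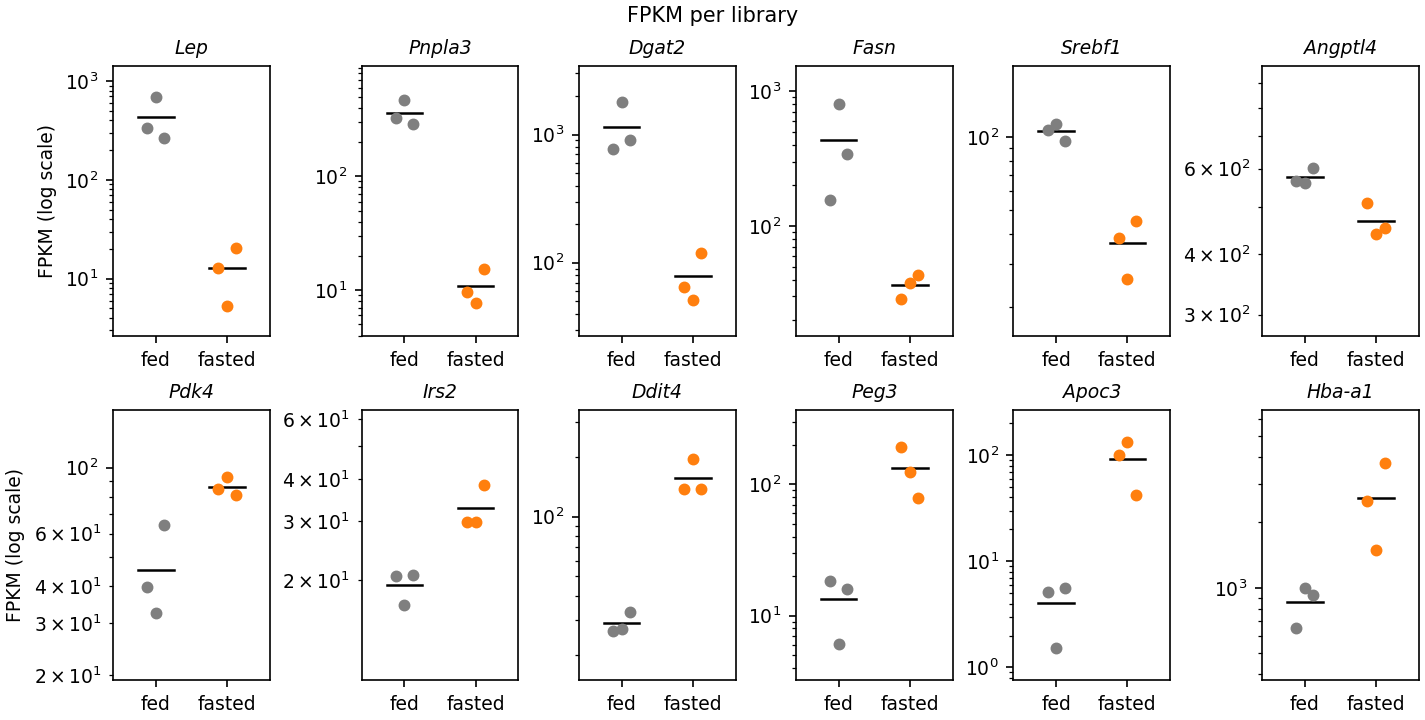
FPKM of 12 genes in each of the 3 fed (grey) and 3 fasted (orange) libraries, on log axes that differ between panels; points are libraries and lines are group means. Lep lay at 264 to 691 FPKM in fed and at 5.32 to 20.2 FPKM in fasted libraries.

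Genes of fatty acid synthesis fell as a group. Of 18 measured members of the list of de novo fatty acid synthesis and desaturation, 16 fell, 1 rose and 1 did not pass, with a median log2 fold change of -1.30. Besides Pnpla3 and Fasn, the falls included Srebf1 (-1.54 ± 0.20), encoding the lipogenic transcription factor SREBP1, Mlxipl (-0.85 ± 0.11), encoding the carbohydrate-sensing factor ChREBP, Thrsp (-2.60 ± 0.44), Acly (-2.02 ± 0.50) and the desaturase gene Fads3 (-1.15 ± 0.18). The 1 rise was Acacb (1.27 ± 0.33), the acetyl-CoA carboxylase whose product restrains mitochondrial fatty acid import. Thrsp, Acly and Acacb were named after their values were seen. Camera called the list lower than other tested genes (adjusted p = 0.00354; adjusted p = 0.527 with an estimated correlation). Over all annotated genes 6 of the falls passed. Fed replicate 2 had the highest fed value for 14 of the 16 genes that fell, with a median ratio to the other fed libraries of 1.80, and without it 16 members fell. As the genes held were chosen on these libraries, these counts are not independent evidence of direction, and this holds for each list below.

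Genes of cholesterol synthesis fell in the same tissue. Of 17 measured members of the list of cholesterol synthesis and SREBP2 targets, 16 fell, 0 rose and 1 did not pass (median -1.26; 4 falls over all annotated genes). Fed replicate 2 was the highest fed library for 15 of these 16, with a median ratio of 1.75, and without it 12 members fell. Falls included Fdps (-1.85 ± 0.25), Nsdhl (-1.46 ± 0.23), Mvk (-1.46 ± 0.19) and Acat2 (-1.21 ± 0.14), enzymes of sterol synthesis. Camera gave an adjusted p = 0.00286 (adjusted p = 0.527 with an estimated correlation). Among 10 members of triglyceride synthesis and glyceroneogenesis, 8 fell and 2 rose. Dgat2, Agpat2 (-1.48 ± 0.26) and Gpd1 (-1.87 ± 0.36) fell, whereas Pck2 (1.24 ± 0.15) and Dgat1 (0.73 ± 0.16) rose, the latter named after its values were seen. Of 6 members of lipolysis and lipid droplet, 5 fell, among them the lipid droplet coat gene Plin1 (-1.17 ± 0.23), Mgll (-0.65 ± 0.15) and Prkar2b (-1.47 ± 0.19), and Pde3b rose (0.72 ± 0.18). Without fasted replicate 2, and with median-ratio scaling, 3 of those falls passed. Camera called neither of these lists. Over all annotated genes 1 rise and 1 fall of the triglyceride list and 1 fall of the lipolysis list passed.

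In fatty acid uptake and transport, 5 of 8 measured members fell, 2 rose and 1 did not pass. The caveolin genes Cav1 (-1.98 ± 0.13) and Cav2 (-1.76 ± 0.19) fell, while the fatty acid transporter gene Slc27a1 (2.19 ± 0.32) and Gpihbp1 (0.97 ± 0.15), which holds lipoprotein lipase on capillaries, rose. Angptl4, an inhibitor of lipoprotein lipase, was 576 ± 21.5 FPKM in fed and 468 ± 37.6 in fasted tissue (log2 fold change -0.30 ± 0.12, adjusted p = 0.0424). That call was lost with median-ratio scaling (adjusted p = 0.475, with a range of 0.0132 to 0.785 over all alternatives), without any single fed library and without fasted replicate 2 or 3. Of 13 members of mitochondrial and peroxisomal fatty acid oxidation, 7 rose, 5 fell and 1 did not pass. The rises included Acad11 (0.99 ± 0.20), Ehhadh (1.2 ± 0.26), Slc25a20 (0.83 ± 0.14), the carnitine-acylcarnitine carrier gene, and Acadl (0.47 ± 0.10). The falls were small, from -0.33 to -0.54. They numbered 1 with median-ratio scaling, 0 with quantile scaling, and 3 without fed replicate 3 or fasted replicate 2. Camera called neither list, and over all annotated genes 2 rises and 2 falls of the uptake list and 1 rise of the oxidation list passed.

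Of 12 measured PPAR and FOXO targets, 8 rose, 3 fell and 1 did not pass (median 0.75, camera adjusted p = 0.0921). Pik3ip1 (1.15 ± 0.15), Sesn1 (1.08 ± 0.22), Fbxo32 (0.85 ± 0.14) and Irs2 (0.72 ± 0.15), encoding an insulin receptor substrate, rose. Pdk4, a kinase that blocks pyruvate oxidation, went from 45.4 ± 16.7 to 86.1 ± 6.12 FPKM (0.96 ± 0.23; adjusted p = 0.00836, and 0.155 over all annotated genes). Without fed replicate 1, and with median-ratio scaling, 1 of the 3 falls passed. The stricter adjustment over all annotated genes left 1 rise and 0 falls of this list by limma. Of 21 glucocorticoid-responsive genes listed, 5 were measured and all rose (camera adjusted p = 0.0159, and 0.527 with an estimated correlation). They were Ddit4 (2.38 ± 0.17), an inhibitor of mTORC1 signalling, Sgk1 (1.59 ± 0.31), Nfkbia (1.17 ± 0.14), Per1 (0.98 ± 0.15) and Pdk4, and 3 passed over all annotated genes. The 4 measured circadian clock genes rose, among them Per1, Npas2 (1.24 ± 0.31) and Rora (0.41 ± 0.16). Rora missed the threshold with quantile scaling, with the shift, and without fed replicate 1 or 3 or fasted replicate 1 or 2 (adjusted p of 0.0507 to 0.118). Time of tissue collection is not given in the sources used here. Of the thermogenesis list, Ppargc1a (0.90 ± 0.24) and Ppargc1b (0.69 ± 0.20) were measured and rose, and by limma neither passed over all annotated genes (adjusted p = 0.202 and 0.285).

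Glycolytic genes were mostly lower. Of 14 measured members, 11 fell, 1 rose and 2 did not pass (median -0.63). Tpi1 (-1.63 ± 0.19), Pgam1 (-0.999 ± 0.16), Ldha (-0.996 ± 0.18) and Pfkl (-0.80 ± 0.15) fell, and Eno3 (0.88 ± 0.24), named after its values were seen, rose. Camera gave an adjusted p = 0.0415 (adjusted p = 0.527 with an estimated correlation), and 0.058 without fasted replicate 1 (0.0277 to 0.058 over the libraries left out). In the TCA cycle and pyruvate entry 8 of 9 members fell, led by Cs (-0.58 ± 0.12), Mdh1 (-0.60 ± 0.13), Idh3a (-0.82 ± 0.18) and Pdhb (-0.82 ± 0.19). In nuclear-encoded oxidative phosphorylation 7 of 9 fell, led by Ndufb3 (-0.95 ± 0.16) and Cycs (-0.68 ± 0.13). Falls in the TCA list numbered 4 with median-ratio and 3 with quantile scaling, and 5 without fasted replicate 2. Cs and Mdh1 missed the threshold with quantile scaling. Those in oxidative phosphorylation numbered 2 with either scaling and without fasted replicate 2, and 4 without fed replicate 2. Camera called neither list (adjusted p = 0.0563 and 0.0875), and over all annotated genes by limma no member of either passed (0), against 2 falls of the glycolysis list.

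Insulin signalling genes went both ways, with 5 rises and 5 falls among 10 members. Slc2a4, encoding the insulin-regulated glucose transporter GLUT4 (-0.96 ± 0.14), the phosphatidylinositol 3-kinase subunit gene Pik3r1 (-1.78 ± 0.15) and Grb14 (-1.53 ± 0.25) fell, and Grb10 (1.14 ± 0.23) rose. The list's median was 0.09, its mean -0.12, camera's direction up (adjusted p = 0.951) and fry's down (adjusted p = 0.00503, tested against no change rather than against other genes). With median-ratio scaling 3 falls passed, and without fed replicate 3 there were 3 rises. Ketone body and branched-chain amino acid catabolism had 3 rises, among them Bckdhb (0.79 ± 0.14) and Ppm1k (1.09 ± 0.21), and 3 falls, among them Oxct1 (-1.02 ± 0.20). With median-ratio scaling 1 of the falls passed. Autophagy and lysosome genes divided evenly, with 6 rises, such as Ulk1 (1.18 ± 0.12), the autophagy-initiating kinase gene, and Bnip3 (0.90 ± 0.17), and 6 falls, such as Ctsb (-1.0 ± 0.18) and Lamp1 (-0.77 ± 0.15). Camera called none of these 3 lists. The stricter adjustment over all annotated genes left 2 insulin signalling falls, 1 ketone body rise and 1 autophagy rise.

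Secreted factors of adipose tissue were mostly lower, with 12 falls and 2 rises among 14 members (median -1.38). Beside Lep, the falls included the acute-phase genes Hp (-2.02 ± 0.22) and Orm1 (-2.14 ± 0.38) and the imprinted gene Nnat (-2.0 ± 0.27); the rises were Fst (1.31 ± 0.24) and Apoe (0.90 ± 0.22), named after their values were seen. Of 21 adipocyte identity genes listed, 6 were measured and all fell, including Aoc3 (-1.89 ± 0.22), Mrap (-1.19 ± 0.14), Tshr (-0.94 ± 0.17) and Plin1. Camera missed the threshold for both lists (adjusted p = 0.0552 for each). Orm1 has close copies and is uncertain. Camera's adjusted p fell under the threshold for secreted factors without fed replicate 1 or 2 or fasted replicate 3 (0.0388 to 0.0792 over the libraries left out), and for adipocyte identity without fasted replicate 3 (0.0182 to 0.0748). It was also under the threshold for secreted factors with median-ratio (0.0363) and quantile scaling (0.0466), and for adipocyte identity with median-ratio scaling (0.0458). The stricter adjustment over all annotated genes left 3 and 2 falls.

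Extracellular matrix genes fell. Of 20 measured members, 17 fell and 3 rose, with a median of -0.96, and 8 falls passed over all annotated genes. Collagen genes led the falls, with Col15a1, Col3a1 (-1.34 ± 0.11), Col5a1 (-1.50 ± 0.20) and Col4a1 (-0.96 ± 0.12), and the rises were Eln (1.40 ± 0.20), Mmp14 (1.01 ± 0.19) and Postn (0.89 ± 0.20), named after their values were seen. Among the collagen genes of this list Col1a1 (-0.36 ± 0.15) and Col1a2 (-0.38 ± 0.14) fell least (limma adjusted p = 0.0499 and 0.0356). Both were named after their values were seen. Of 14 genes named Col, 13 fell and 1 rose, and 11 fell with median-ratio or quantile scaling. Camera gave an adjusted p = 0.0182 (adjusted p = 0.527 with an estimated correlation).

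Of 43 ribosomal protein genes listed, 25 were measured and all rose, with a median log2 fold change of 0.53 and a range of 0.42 to 0.82. The lower end of that range lies near the upper edge (0.45) of the nearly empty interval of ratios. Smaller rises were therefore unlikely to be among the genes held, and the narrow range is partly built in. Rps27 (0.82 ± 0.14), Rpl37 (0.72 ± 0.13), Rpl3 (0.59 ± 0.12) and Rps14 (0.70 ± 0.14) had the smallest p. Camera gave an adjusted p = 1.66e-05 (adjusted p = 0.527 with an estimated correlation). None (0) passed over all annotated genes by limma and 6 did over protein-coding genes. The unadjusted p was under the threshold for all 25, as it was for 2753 of the 2999 genes tested. Ribosomal protein genes have many processed pseudogenes, so their values are uncertain.

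The amino acid and ER stress list had 12 falls, 5 rises and 1 member that did not pass among 18. Trib3 (2.0 ± 0.20), Chac1 (1.45 ± 0.29), Asns (1.09 ± 0.18), Sesn2 (1.08 ± 0.26) and Slc3a2 (0.83 ± 0.23) rose. Falls included the ER chaperone gene Hspa5 (-1.05 ± 0.14) and Edem1 (-1.11 ± 0.13), and the serine synthesis genes Psph (-1.74 ± 0.21), Phgdh (-1.26 ± 0.27) and Psat1 (-0.77 ± 0.14) and the mitochondrial folate enzyme gene Mthfd2 (-0.79 ± 0.27). Apart from Trib3, Psph, Edem1 and Hspa5, these genes were named after their values were seen. Of 8 immediate early genes, 4 rose, 2 fell and 2 did not pass, and adjusted over the list alone 3 rose. Ier2 rose (0.70 ± 0.14) and Fos (-0.64 ± 0.19) and Atf3 (-0.80 ± 0.23) fell, while Fos missed the threshold with median-ratio scaling and rises numbered 2 without fed replicate 2 and without fasted replicate 1 or 2. Camera called neither list. The stricter adjustment left 1 rise and 3 falls of the stress list and no immediate early gene (0; 6 had passed over the genes tested).

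Vascular and blood cell markers were mostly higher. Of 8 endothelial markers, 7 rose, including Eng (1.04 ± 0.14), Pecam1 (0.94 ± 0.17) and Emcn (0.50 ± 0.12), and Aqp1 fell (-0.57 ± 0.11, a call lost with quantile scaling). Of 13 erythroid genes listed, 5 were measured and all rose. Hba-a1 went from 861 ± 180.4 to 2590 ± 1142 FPKM (1.51 ± 0.33), and Hbb-bs (1.45 ± 0.32), Hba-a2 (1.45 ± 0.34) and Hbb-bt (1.39 ± 0.40) rose too, near-copies whose reads may be divided between them. Camera missed the threshold for both lists (adjusted p = 0.0552 for each). Without fasted replicate 2 it called the erythroid list (0.0035, with a range of 0.0035 to 0.0946 over the libraries left out). With quantile scaling it called both lists (0.0361 for endothelial and 0.0466 for erythroid genes), and with median-ratio scaling the endothelial list (0.0458). Over all annotated genes by limma 1 endothelial and no erythroid gene (0) passed. Of 10 smooth muscle and pericyte markers 7 rose, such as Actg2 (2.11 ± 0.42), Abcc9 (0.86 ± 0.18) and Kcnj8 (1.21 ± 0.25), and 3 fell, such as Synpo2 (-1.54 ± 0.20). Camera did not call this list (adjusted p = 0.214), and over all annotated genes by limma 0 rises and 1 fall passed. These lists moved beside the falls in adipocyte genes above.

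Of 8 fibroblast and adipocyte progenitor markers, 5 rose, among them Dcn (1.06 ± 0.24) and Icam1 (0.66 ± 0.15), and 3 fell, among them Col15a1 and Sema3c (-1.03 ± 0.23). The median was 0.73, but the mean was -0.16. Inflammatory cytokines and chemokines comprised 4 rises, including Ccl5 (1.35 ± 0.21) and Cxcl12 (0.95 ± 0.17), and 3 falls, including the monocyte chemoattractants Ccl2 (-1.41 ± 0.24) and Ccl7 (-1.50 ± 0.30). Of 7 interferon-stimulated genes, 4 fell, among them Zbp1 (-0.71 ± 0.15), Gbp2 (-0.66 ± 0.25) and Rtp4 (-0.50 ± 0.21), and 3 did not pass. Adjusted over the list alone 2 fell, with median-ratio scaling 1 did, with the shift 7 did, and without fed replicate 2 or 3 or fasted replicate 2 or 3, 2 did. Gbp2 and Rtp4 missed the threshold without any single fed library and without fasted replicate 2 or 3. The change of Gbp2 was -0.35 without fasted replicate 2. Camera called none of these 3 lists. Over all annotated genes by limma, 1 fall of the fibroblast list, 1 rise of the chemokine list and no interferon-stimulated gene (0) passed.

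Markers of immune cells were few. Of 3 macrophage markers, Mpeg1 rose (0.96 ± 0.19), Itgam fell (-1.03 ± 0.25) and Lyz1 did not pass (-0.68 ± 0.29); adjusted over the list alone 2 fell. Lyz1 was -0.45 without fed replicate 2 and passed without fed replicate 1 or fasted replicate 2. The neutrophil gene S100a8 fell (-2.02 ± 0.26), the dendritic cell gene Zbtb46 rose (0.60 ± 0.18), and the mesothelial gene Efemp1 (-0.97 ± 0.33) and the myelin gene Pmp22 (-1.34 ± 0.21) fell, each the only measured member of its list. Efemp1 missed the threshold under both other scalings and without fed replicate 2 or 3 or fasted replicate 1 or 3. Over all annotated genes by limma, S100a8 and Pmp22 passed. Mpeg1, Itgam, Zbtb46 and Efemp1 did not (adjusted p = 0.0883, 0.16, 0.325 and 0.437). No member (0) of the cell cycle, T and NK cell, B and plasma cell, skeletal muscle, epididymal epithelium and testis lists was tested here. Except where stated, counts adjusted over the list alone equalled those over all genes tested.

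**Figure D3:**
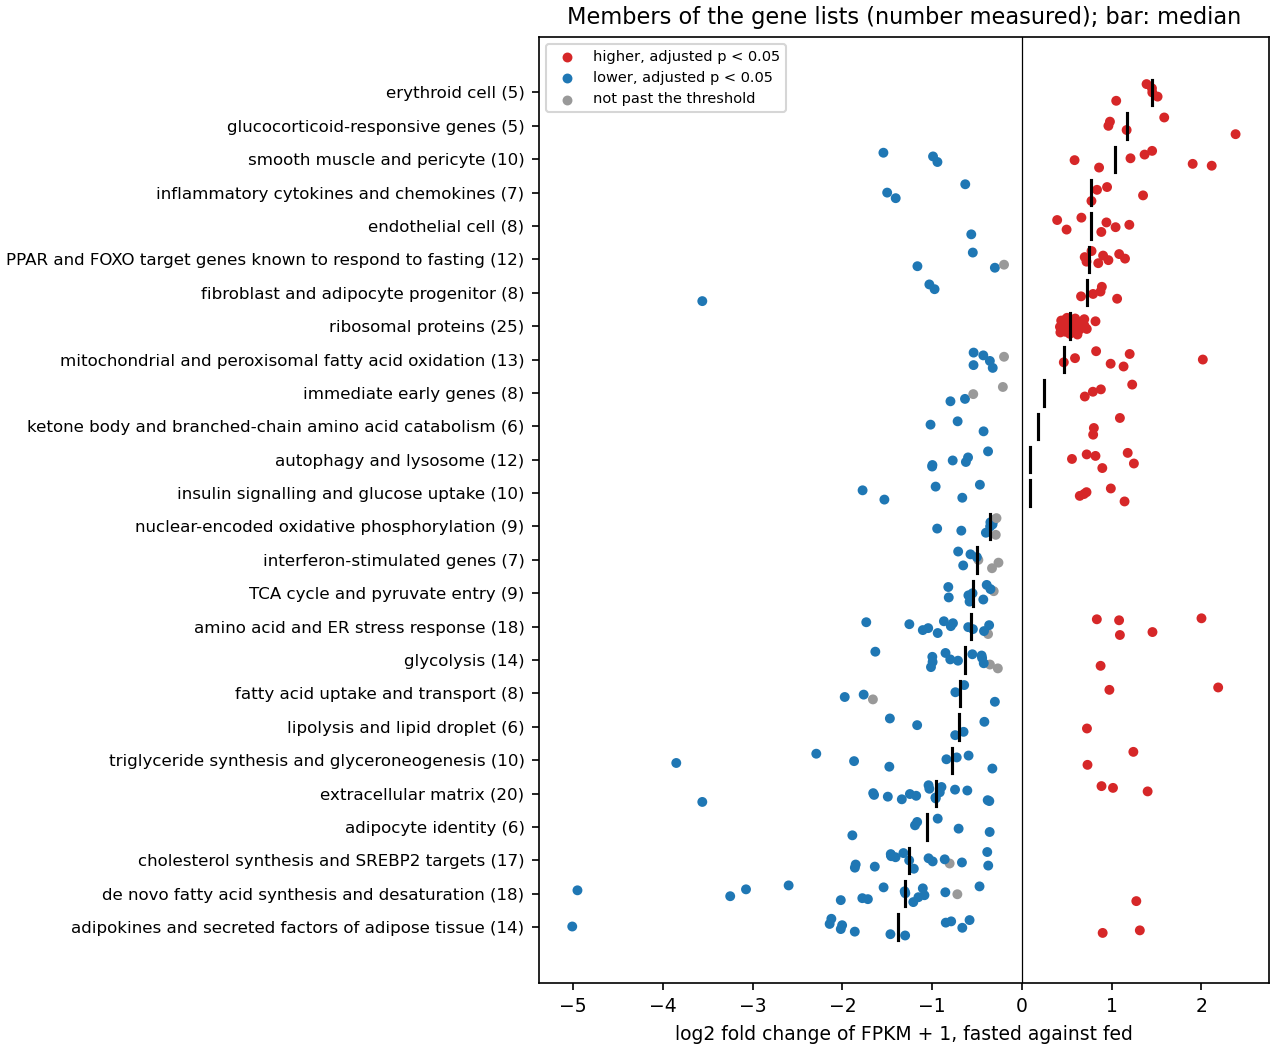
Log2 fold change (fasted against fed, FPKM + 1) of each measured member of the lists with at least 5, with the number measured in brackets; red and blue points passed an adjusted p of 0.05 as higher or lower, grey points did not, and bars are medians. Medians ran from -1.38 for secreted factors to 1.45 for erythroid genes, and the 25 ribosomal protein genes lay between 0.42 and 0.82.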

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

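The stricter adjustments and the shift were chosen only after the results were seen; the other alternatives were planned. The counts of genes higher and lower were 557 and 495 when adjusted over all annotated protein-coding genes, 172 and 192 over all annotated genes, and 340 and 348 with a log2 fold change of at least 1 in size; with median-ratio scaling 787 were lower. That minimum left 564 and 236 with median-ratio scaling, 382 and 326 with quantile scaling, and 254 and 431 with the shift. Leaving out 1 library at a time gave 1128 to 1230 higher and 1036 to 1302 lower genes. Lists called higher and lower by camera numbered 2 and 4. They numbered 0 and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05 and the smallest was 0.0989, and 5 and 14 by fry, which tests against no change and not against other genes; with quantile scaling 4 were higher. Leaving out 1 library gave 2 to 3 lists higher and 3 to 6 lower. Over the 131 named genes, 0 of 2085 comparisons with an alternative reversed direction. Many could not reverse, because the stricter adjustments, the variance options and the filters leave the fold change as it was. Where the groups did not overlap, leaving out 1 library could not reverse it either. Among all genes called, 1 changed direction with quantile scaling. Calls lost numbered 74 over all annotated genes, 25 over protein-coding genes, 9 with quantile and 8 with median-ratio scaling, and 3 to 7 without 1 library. The stricter adjustments lose calls by construction, and for the other settings the cause was not tested. Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split called 2714 genes and 1 of the 10 splits, the real one, called as many; the highest other called 0 by limma, with 90 genes at an unadjusted p under 0.05. The genes had been chosen for the real split, so this contrast is partly built in. Depth is unknown, so its effect on small changes could not be measured.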

Other observations

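The gene families in the first paragraph were looked at only after their values were seen, as were the tests of mean level, of the ribosomal protein genes and of adipocyte share. For 56 overlapping name groups, rises and falls among called genes were set against all other called genes by Fisher's exact test, adjusted by Benjamini-Hochberg over the 56. Genes are not independent replicates, and all had been chosen on these libraries. Of 20 genes with heat shock protein names, which include the binding protein gene Hspbp1, 18 fell and 2 rose (adjusted p = 0.0077). Of 22 mitochondrial ribosomal protein genes 18 fell, 1 rose and 3 did not pass (adjusted p = 0.00272). They were opposite in direction to the 48 cytosolic ribosomal protein genes, which all rose (adjusted p = 1.16e-15, and 47 passed with the shift). Coat proteins of ER and Golgi vesicles had 12 falls and 1 rise (adjusted p = 0.0414). Neither of the simpler name patterns passed, with 7 falls for genes named Cop (adjusted p = 0.0789) and 9 falls and 1 rise for genes named Sec (adjusted p = 0.106). ER chaperones, disulfide isomerases and prolyl hydroxylases matched by name had 11 falls and 0 rises (adjusted p = 0.0089). All 6 genes of the narrow apolipoprotein pattern (families A and C to E) rose (median log2 fold change 1.73; adjusted p = 0.0414; 5 with quantile scaling), but the wider set of 9 genes named Apo had 6 rises and 3 falls (adjusted p = 0.504), and zinc finger genes named Zfp had 28 rises and 8 falls (adjusted p = 0.00177). The 6 genes grouped as acute-phase fell (median -2.15). They were Hp, Lrg1, the close copies Orm1, Orm2 and Orm3, and the metalloreductase gene Steap4. The group missed the threshold (adjusted p = 0.131), as did 15 imprinted genes, with 8 rises and 6 falls (adjusted p = 0.591). The groups described here kept their direction under the other scalings, but this is no support. Among all genes called only 1 changed direction, with quantile scaling, so groups could hardly do so. Fisher's test was not repeated under those scalings. With median-ratio scaling the falls numbered 12 for heat shock, 7 for mitochondrial ribosomal, 4 for coat and 6 for ER chaperone genes. Over all annotated genes, 364 of the 2999 genes tested passed by limma. In these groups 2 of 20 heat shock, 4 of 39 Zfp and 2 of 11 ER chaperone genes did. So did 1 of 6 apolipoprotein, 3 of 6 acute-phase and 3 of 15 imprinted genes. No (0) ribosomal, mitochondrial ribosomal or coat gene passed.

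The fed libraries differed among themselves in lipogenic genes. Fed replicate 2 had the highest value of the fed libraries for 14 of the 16 fatty acid synthesis genes that fell and 15 of the 16 cholesterol genes, with median ratios to the other fed libraries of 1.80 and 1.75. Of the other 1450 genes that fell it was the highest for 904 (62.3%; median ratio 1.15), and of the 1232 genes that rose for 238 (19.3%). No explanation of this spread was tested.

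The ratios of group means left a sparse interval from -0.21 to 0.45 on the log2 scale, whose midpoint was 0.118 and not 0. The edges were taken at the 1% quantile on each side, and the midpoint was 0.123 at 2% and 0.118 at 10%. A bias that depends on mean level is argued against as the reason for this midpoint only. The midpoints of 4 classes of genes by mean FPKM spanned only 0.021. A bias shared with the values on which the genes were chosen would leave the midpoint in place, so it could not be tested this way. Positive and negative ratios numbered 397 and 353 in the lowest class by mean FPKM, and 255 and 495 in the highest. The midpoints of 3 classes by combined length of annotated exons spanned 0.016. One scaling difference between these values and those on which the genes were chosen therefore stays open as a candidate explanation. If so, fasted values may read about 8.5% too high relative to that scale.

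The shared rise of cytosolic ribosomal protein genes was weighed against 2 technical explanations. The 419 other genes nearest to them in length had a median log2 fold change that differed from that of the remaining genes by -0.032 (95% bootstrap interval -0.09 to -0.002). Length here was that of all annotated exons of a gene combined, which can exceed that of its expressed transcript. The prediction for a bias by length was a difference of at least 0.437, a bar set after the values were seen. A bias that follows this combined length is argued against as the main cause. One that follows the expressed transcript could not be tested, and the compared genes had also been chosen for differing. With the fasted libraries shifted by the midpoint, 25 of 25 genes of the fixed list still passed. That outcome was nearly certain, as 1211 genes of all kinds were higher with the shift, against 1232 without it. Passing therefore says little about ribosomal protein genes in particular. The shift of 0.118 was smaller than each of their rises (0.42 to 0.82), which argues against that scaling difference as the whole cause. Reads shared with pseudogenes and a bias by expressed transcript length were not tested and stay open, as does an effect of fasting itself as a hypothesis.

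All 5 red cell, 7 of 8 endothelial and 7 of 10 smooth muscle genes measured rose, and all 6 adipocyte identity genes measured fell. Those lists name 13, 19, 14 and 21 genes, and the rest were not analysed here. Camera called none of these lists (adjusted p = 0.0552, 0.0552, 0.214 and 0.0552). A lower share of adipocytes as the only cause would raise markers of other cell types alike, but the red cell median (1.45) exceeded the endothelial one (0.77; exact two-sided permutation p = 0.0194 over 5 and 8 genes). That p treats genes as independent, which the globin near-copies are not, and takes no account of the spread between mice. The smooth muscle and fibroblast lists, not part of that test, had medians of 1.03 and 0.73, and 3 of 8 fibroblast markers fell. The log2 ratio of Hba-a1 to Hbb-bs had an SD of 0.085 over the 6 libraries, but any cause acting on 1 cell source of both genes would keep that ratio, so it favours none. More blood in the fasted pieces stays open for the red cell genes only. If it raised them, the difference of medians does not speak against a lower adipocyte share for the other lists. For the other genes a lower adipocyte share, alone or with another cause, or an effect of fasting on these cells, stays open.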
